A study of Homo sapiens with 2 samples.

How the data were processed

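Ribosome-protected fragments were measured in 2 libraries of HEK293 cells, both vehicle controls. Per the labels' protocols, cells from 2 plates of 15 cm per sample were lysed with cycloheximide present, lysates were digested with RNase I, monosomes were isolated on size-exclusion columns, and fragments of 20 to 38 nt were cut from a gel without depletion of ribosomal RNA before adapter ligation, amplification and paired-end sequencing. Without such depletion, fragments of ribosomal RNA enter the library and can take up depth.

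The deposited table gives, per the labels and the series' design text, counts of fragments of 27 to 29 nt for each Ensembl gene ID, with 1 column per library and no scaling. Some deposited values are not whole, so the authors' values were treated as estimated counts of fragments per ID: 15.2% of the values above 0 in replicate 1 and 13.9% in replicate 2 differed from a whole number by more than 0.001. Of these values, 87.0% had a fractional part of 0.5, 8.10% of 0.33 or 0.67 and 3.10% of 0.17 or 0.83. Division of some fragments over more than 1 feature or place would give such values, but this was not tested. The genome build was hg19, per the submitters' processing notes. The aligner, the counting tool, the annotation, the strand setting and any rule that divides fragments are not given in the sources used here. IDs that overlap on the genome or share sequence with near-identical copies may therefore carry an uncertain split.

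The reference table used here (59792 genes) lists an Ensembl ID for 0 genes, and 0 of the 57820 IDs of the count table occur in any of its columns. The 30 gene lists (751 entries) fixed before the data were examined therefore could not be applied, nor could coding length, GC content or gene class. The rule for named genes, also fixed before the data were examined, took the 15 highest IDs by mean CPM and the 10 most extreme IDs in each direction between the libraries. Because IDs could not be named, only the first 2 of each are printed. Every row of the table carried an Ensembl ID, so none was removed from the library sizes.

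CPM and shares were computed from the deposited values over the sum of all IDs, and intervals of shares are exact Clopper-Pearson intervals at 95%. For scaling factors, dispersions, the chi-square statistic, the abundance bins and the ratios of single IDs, values were rounded to whole numbers, and 0.5 was added to both counts for median ratios within bins and within sets of IDs. Scaling factors were TMM factors from edgeR 4.0.16 (R 4.3.3) over IDs with a summed count of at least 20. Pearson and Spearman correlations were measured on log2(CPM + 1). The median absolute log2 ratio and the shares within 1.5-fold and 2-fold used ratios of TMM-scaled CPM without that pseudocount. Intervals of these measures came from 1000 bootstrap draws over IDs. The common dispersion was estimated with edgeR from an intercept-only design. With 1 group there was no contrast to test. Single IDs with a summed count of at least 100 were given the ratio of replicate 2 over replicate 1 with a conditional exact binomial interval. These intervals hold counting error only, not the spread between libraries.

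The steps were tested on simulated data. From counts simulated with the 6965 real means and coefficients of variation of 0.1, 0.2 and 0.4, edgeR estimated 0.101, 0.197 and 0.396. With 200 IDs changed between the 2 simulated libraries, drawn from IDs with a real summed count of at least 200, and counting error only, the 2-fold rule found 100% of 4-fold changes, 100% of 8-fold changes and 1.5% of exact 2-fold changes, with 0 false calls. With the estimated common dispersion added it found 86% of 4-fold and 99% of 8-fold changes, with 28 and 33 false calls.

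Replicate 1 held 865838 counts and replicate 2 held 611266, so 10 counts correspond to 11.5 CPM and 16.4 CPM. Alternatives planned before the data were examined were library-size and DESeq2 1.42.0 scaling, other count minimums, pseudocounts of 0.5 and 5 CPM, the DESeq2 dispersion trend, a 1.5-fold limit, 99% intervals, the 10 highest IDs left out, and each replicate left out. Those chosen after seeing the data left out the 2 highest IDs, the IDs with non-whole counts, or the last 50 IDs of the table. Calculations outside R used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.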

Results

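The series holds ribosome profiling of HEK293, an established human embryonic kidney cell line. In this assay, RNase I trims mRNA outside bound ribosomes, and the fragments that ribosomes protect are sequenced as footprints of translation. The 2 libraries form a single group, cells kept in DMSO vehicle for 12 h, with replicate 1 from batch 1 and replicate 2 from batch 2. The title of the series asks how densely ribosomes occupy mRNAs that encode aggregating proteins, and where along those mRNAs they sit. Minocycline-treated cells, matched RNA-seq and positions within mRNAs are not analysed here, so neither translational efficiency nor 5′ bias could be measured. The comparisons that remained were between genes within a library and between the 2 vehicle libraries. Genes appear as Ensembl IDs, because the files and the reference table used here do not pair those IDs with names or genome positions.

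Replicate 1 held 865838 counts and replicate 2 held 611266 counts, a ratio of 1.42. Of the 57820 IDs in the table, 12262 had a count above 0 in both libraries, 2682 only in replicate 1 and 1521 only in replicate 2. The other 41355 IDs were at 0 in both libraries, where a count of 0 allows up to 3 counts, or 3.46 CPM (counts per 1000000 counts of the library) in replicate 1 and 4.91 CPM in replicate 2. At least 10 counts were reached by 7546 IDs in replicate 1 and 6347 in replicate 2, and at least 100 counts by 1397 and 889 IDs. Limits and the intervals of shares and of single-ID ratios cover counting error only, and treat fragments as independent. Amplified fragments without molecular identifiers are not independent molecules, so these limits and intervals may be too narrow even for counting error. Nothing in the labels states that the libraries came from independent cultures, beyond their different batch numbers, so the SD over 2 libraries measures the spread between these libraries and may be partly technical.

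Fragment counts were concentrated on 2 IDs in both libraries. Ribosomal RNA was not depleted and IDs could not be named, so whether these counts are footprints on mRNA is not known here. ENSG00000210082.2 held 11.3% ± 3.10 of all counts (SD, n = 2), and ENSG00000211459.2 held 9.13% ± 0.916 (SD, n = 2). ENSG00000210082.2 took 9.08% of replicate 1 (95% exact Clopper-Pearson interval 9.02 to 9.14) and 13.5% of replicate 2 (13.4 to 13.6). Together the pair took 17.6% of replicate 1 (17.5 to 17.6) and 23.2% of replicate 2 (23.1 to 23.4). This difference was larger than the counting error of either library, if fragments are taken as independent. The mean CPM of ENSG00000211459.2 was 10.2 times that of the ID ranked 3. Each of the IDs ranked 3 to 15 held between 0.279% and 0.892% of counts, averaged over the libraries. Of the 15 highest IDs, including the pair, 6 had a higher CPM in replicate 2 and 9 in replicate 1 by library size, and 8 and 7 after TMM scaling.

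The 10 highest IDs held 25.3% ± 4.14 of counts, the 100 highest held 39.9% ± 3.33 and the 1000 highest held 69.2% ± 1.28 (SD, n = 2 for each). On the mean of the libraries, 247 IDs were needed to reach 50% of counts and 4074 IDs to reach 90%. With the 2 highest IDs left out of the total, an alternative chosen after the data were seen, 540 IDs were needed for 50% and 4781 for 90%. The 100 highest of the remaining IDs then held 24.7% of what was left.

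**Figure D1:**
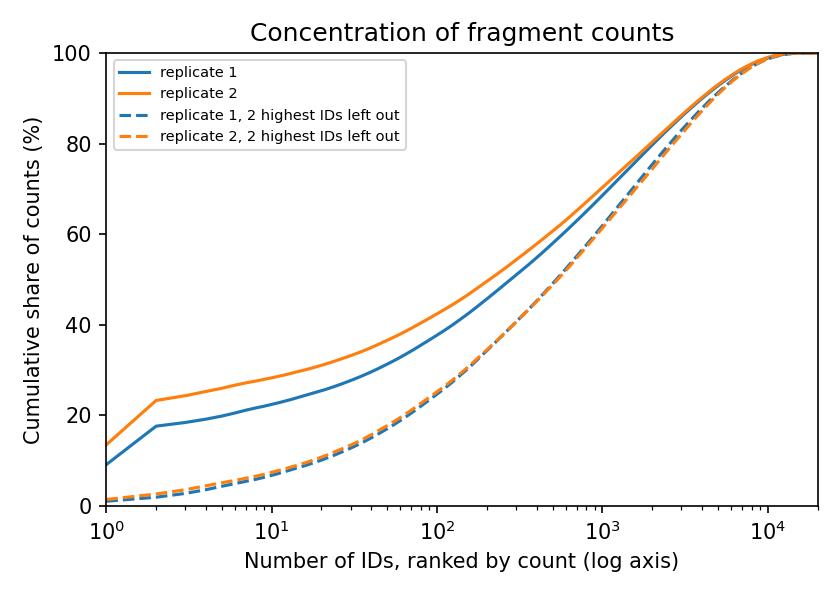
Cumulative share of counts (percent) against the number of Ensembl IDs ranked by count (log axis), for each vehicle library with all IDs (solid lines) and with the 2 highest IDs left out (dashed lines). The solid line starts higher in replicate 2, where the highest ID took 13.5% against 9.08% in replicate 1, and the dashed lines of the 2 libraries lie close together.

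The next comparison was how closely the 2 vehicle libraries agreed for each ID. The shares above were not TMM-scaled, so agreement after TMM scaling does not give their precision. Over the 6965 IDs with a summed count of at least 20, which held 96.1% of all counts, log2(CPM + 1) after TMM scaling had a Pearson r of 0.88 and a Spearman rho of 0.84. These correlations run across genes, which are not independent replicates. The median absolute log2 ratio was 0.44 (95% bootstrap interval over IDs 0.43 to 0.46) among the 6958 of these IDs above 0 in both libraries. Of the 6965 IDs, 62.2% lay within 1.5-fold and 84.1% within 2-fold. The chi-square statistic against sampling of one common profile was 6.03 times its 6964 degrees of freedom, a value that amplified fragments counted more than once would also raise. The deposited values, before rounding, were exactly equal in both libraries for 1.69% of these IDs, and the libraries were counted as separate samples. The common biological coefficient of variation estimated by edgeR from the pair was 0.257, and the median of the DESeq2 dispersion trend gave 0.434.

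Abundant IDs agreed more closely than sparse ones. The 6965 IDs were ranked by summed count and cut into 10 bins of equal size. In the lowest bin, with 20 to 24 summed counts, 69.3% lay within 2-fold and the median absolute log2 ratio was 0.64, where simulated counting error alone gave 0.38. In the highest bin, with 313 or more summed counts, 97.3% lay within 2-fold and the median was 0.24, where counting error alone gave 0.08. The coefficient of variation estimated within each bin was 0.394 in the lowest and 0.197 in the highest.

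**Figure D2:**
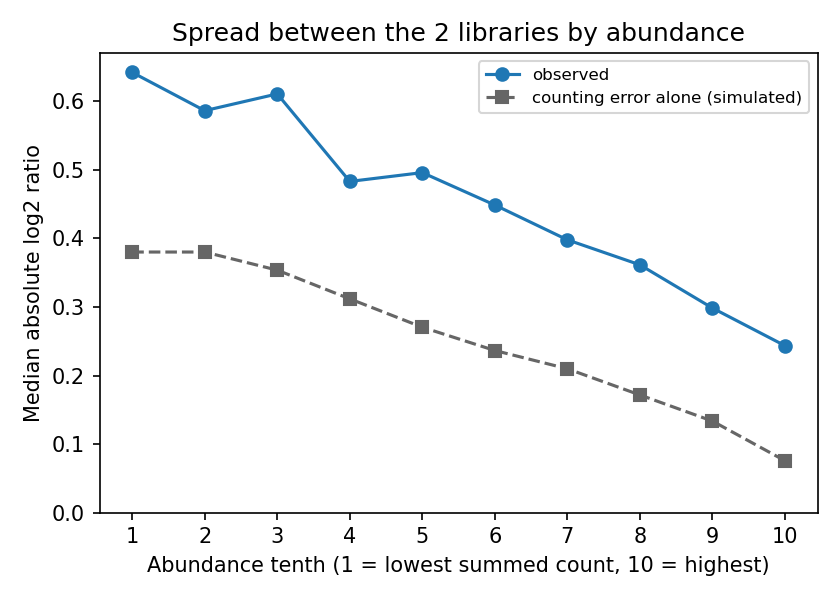
Median absolute log2 ratio between the 2 vehicle libraries (vertical axis) in 10 equal bins of the IDs by summed count, from lowest to highest (horizontal axis). Circles show the observed ratio, falling from 0.64 to 0.24, and squares show simulated counting error alone, falling from 0.38 to 0.08.

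Single IDs were then compared between the libraries. Of 2241 IDs with a summed count of at least 100, 18 had a ratio whose 95% exact binomial interval lay wholly beyond 2-fold: 11 were higher in replicate 2, or 61.1% of the 18, and 7 were higher in replicate 1. Scaling by library size in place of TMM gave 7 and 11, a share of 38.9%, and the median log2 ratio of the 2241 IDs moved from -0.07 to -0.18 (from -0.01 to -0.11 over the 6958 IDs with at least 20 summed counts and above 0 in both libraries). The test compares these 2 libraries, not conditions, and with 1 library per batch the batch and the replicate cannot be told apart. The counts depended on the limits set: a 1.5-fold limit gave 49 higher in replicate 2 and 46 in replicate 1, a minimum of 20 summed counts gave 56 and 29, 99% intervals gave 7 and 4, and leaving out IDs with non-whole counts, an alternative chosen after the data were seen, gave 11 and 4. No p-value was computed.

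ENSG00000201920.1 was the ID furthest towards replicate 2, with 45 counts in replicate 1 and 161 in replicate 2, a log2 ratio of 2.45 (95% interval 1.97 to 2.96). ENSG00000207445.1 followed with 85 and 267 counts and a log2 ratio of 2.26 (1.91 to 2.63). ENSG00000108312.10 was the ID furthest towards replicate 1, with 122 and 22.5 counts and a log2 ratio of -1.86 (-2.59 to -1.20). ENSG00000075292.14 had 124 and 24 counts and a log2 ratio of -1.76 (-2.45 to -1.12). The median difference was 3.45-fold among the 11 IDs higher in replicate 2 and 3.00-fold among the 7 higher in replicate 1. Gene class could not be assigned, so these differences may include RNAs that are not translated. ENSG00000210082.2 and ENSG00000211459.2 were both higher in replicate 2 after TMM scaling, with log2 ratios of 0.68 and 0.31, and both lay within 2-fold; both were also higher in replicate 2 in CPM by library size.

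**Figure D3:**
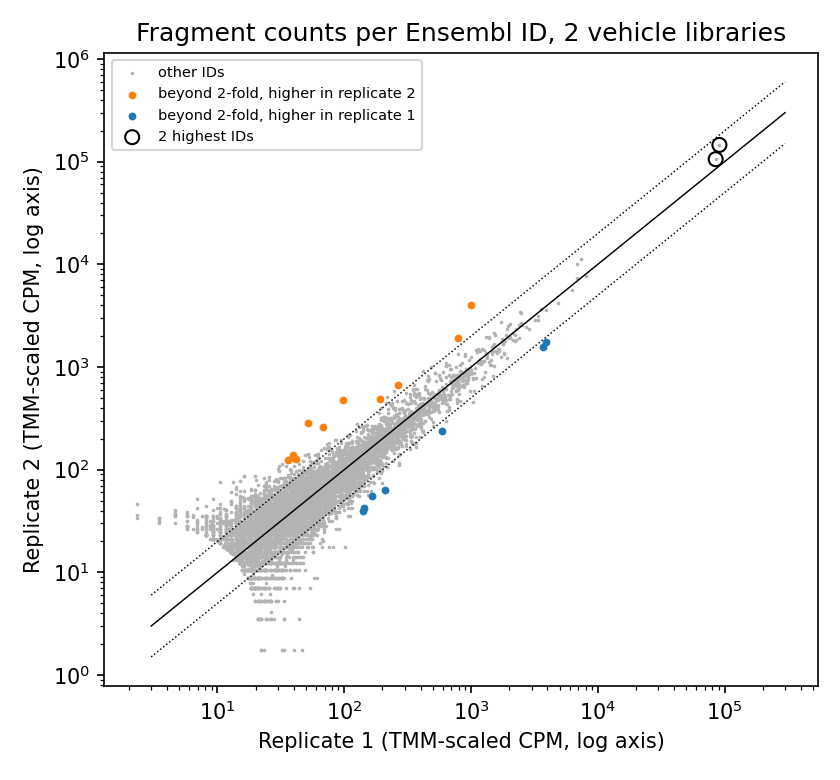
TMM-scaled CPM of each Ensembl ID in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), with the line of equality and dotted lines at 2-fold, for IDs with a summed count of at least 20. Orange points are the 11 IDs beyond 2-fold and higher in replicate 2, blue points the 7 higher in replicate 1, grey points all other IDs, and open circles mark the 2 highest IDs.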

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

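Shares of counts depended on the highest IDs. With the 10 highest left out, the next 1, 10, 100 and 1000 IDs held 0.422%, 3.67%, 20.8% and 59.0% of the rest, and with only the 2 highest left out, 1.13%, 6.89%, 24.7% and 61.4%; these follow from the removal itself. Leaving out 1 library gave the other library's share, within 1 SD of the mean by construction. Agreement depended on the count minimum. With a minimum of only 1 summed count (16059 IDs), Pearson r was 0.85 and the coefficient of variation was 0.299. The median absolute log2 ratio, over IDs above 0 in both libraries only, was 0.55. Of the 16059 IDs, 39.3% lay within 1.5-fold and 53.4% within 2-fold, with IDs at 0 in 1 library counted as beyond. With at least 100 summed counts, r was 0.92, the coefficient of variation 0.208 and the median 0.30. The shares were then 79.0% within 1.5-fold and 95.2% within 2-fold. A pseudocount of 5 CPM gave an r of 0.90. The median of the DESeq2 dispersion trend gave 0.434, and the cause of the gap to edgeR was not tested. Without IDs of non-whole counts, r was 0.87, with 60.7% within 1.5-fold and 83.1% within 2-fold. Spearman rho stayed within its bootstrap interval under each alternative run. Counts of single IDs higher in replicate 2 and in replicate 1 (11 and 7) became 7 and 11 by library size, 49 and 46 at 1.5-fold, 7 and 4 with 99% intervals, 56 and 29 with at least 20 summed counts, and 11 and 4 without IDs of non-whole counts. DESeq2 scaling, the 2 highest IDs left out, and the last 50 IDs left out each gave 11 and 7. Gene lists, coding length, GC content and gene class, fixed beforehand as alternatives, were not run, because IDs could not be paired with names. Depth limits the sparse IDs: with 20 to 24 summed counts, counting error alone gave a median absolute log2 ratio of 0.38.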

Other observations

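The tests of the last 50 IDs, of the median ratio with the highest or last IDs left out, of the spread of the tested IDs and of neighbouring called IDs were chosen after the results were seen. Those of counting error, of the spread of all IDs and of non-whole counts were written down first. The design holds 1 group, so no biological explanation was tested. Both patterns weighed below compare single libraries that differ in batch.

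The 2 highest IDs, ENSG00000210082.2 and ENSG00000211459.2, stand 2 places apart near the end of the table and held a larger share in replicate 2. The last 50 IDs of the table held 19.8% of counts in replicate 1 and 26.0% in replicate 2, and 2.18% and 2.78% without the pair. In the mean over libraries these 50 held 22.9%, against 1.02% for the next of 1156 blocks of 50 IDs. Of the 23 other IDs among the last 50 with at least 20 summed counts, 20 were higher in replicate 2 after TMM scaling. Their median log2 ratio was 0.43 (range -1.79 to 0.961), above all of 10000 random sets matched on mean count, whose central 95% ran from -0.26 to 0.13. The block was chosen because it holds the pair, and the random sets were not matched on place in the table. Neighbouring IDs may not vary independently, so this rank is a description only. The pair may share a source with its neighbours in the table that contributed more to replicate 2, but what these IDs encode is not known here, and batch and replicate cannot be told apart.

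By library size, the median log2 ratio of the other IDs with at least 20 summed counts was -0.11 (95% bootstrap interval -0.13 to -0.09). It was -0.012 (-0.031 to 0.0086) with the 2 highest IDs left out of the library size, and 0.00014 (-0.016 to 0.020) with the last 50 IDs left out. The change with the 2 highest left out follows in full, by arithmetic, from the shares those 2 IDs took in each library. Most of the change with the last 50 left out follows in the same way from their shares.

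It stays open whether the 18 IDs beyond 2-fold exceed a spread common to all IDs. Simulations with the dispersion of all 6965 IDs gave 22 to 46 such IDs, more than were seen. That coefficient of variation, 0.257, is wider than the 0.208 of the tested IDs, so these simulations overstate the number to be called. Simulations with the dispersion of IDs of at least 100 counts gave 2 to 17. The 18 seen lay just above the highest of these, a margin too small to settle the question. Simulations with counting error alone gave 0 in each of 100 draws, below the 18 seen. This argues against counting error of independent fragments as the only source of the 18 as a set. Amplified fragments counted more than once would widen counting error, and these draws do not cover that. The 2-fold rule itself leaves almost no such IDs without added spread, so the draws say nothing about which single IDs differ. Division of fragments among features is also open as a candidate explanation: 3 of the 18 had a non-whole count, against 485 of the 2241 tested, with a Mantel-Haenszel odds ratio of 0.70 over abundance strata (95% interval 0.198 to 2.47). All 3 were higher in replicate 1, and 2 of them stood 6 places apart in the table and had near-equal counts, 3343.5 and 993.5 against 3180 and 879.5 in replicates 1 and 2. Within 5 places no called ID had a neighbour called in the same direction. Within 10 places these 2 were the only ones, which 1.3% of 10000 random choices of 7 tested IDs matched (2.25% within 20 places). These windows were tried after the results were seen, with the pair 6 places apart, so the percentages cannot count as support.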
